A study of Mus musculus with 24 samples.

How the data were processed

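RNA bound by STAU2 was recovered from mouse embryonic cortex by RNA immunoprecipitation (RIP) and sequenced beside RNA of the input lysate. The labels list 24 libraries in 8 groups: STAU2 RIP and input, with 3 libraries each, at E11.5, E13.5, E15.5 and E17.5. Per the labels' protocols, each biological replicate started from cortices pooled over a litter, RNA was treated with DNase, and libraries were made with a ScriptSeq kit, which keeps the strand of the RNA. A RIP with an antibody against the T7 tag was read out by qPCR only, and that readout was not analysed here. RIPs from sorted TBR2-positive cells, which the protocol text also covers, were not analysed here.

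The values used were 8 deposited peak lists, 1 per time point and strand. The labels of every RIP and input library of a time point point to the same pair of lists, so the 3 RIP and 3 input libraries stand behind 1 list and no replicate has a list or a column of its own. Coordinates are in mm10, per the labels. The submitters' processing notes name TopHat2 2.0.9, TopHat, bedtools 2.17.0 and Cufflinks 2.2.1 without saying what each did. The peak caller and the statistical test behind the peaks are not given in the sources used here.

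Each peak carries 4 values that the authors deposited without column names. The deposited score is a whole number that fell as the q-value rose, with a Spearman correlation between -1.00 and -0.998 in the 8 lists. The deposited signal is a positive value per peak whose product with 3 times the peak width was a whole number of thousandths in 100% of peaks, as a mean over the bases of a peak and over 3 libraries would give; which libraries and what scaling lie behind it is not stated. The deposited p-value and q-value per peak are the authors' own: in 93.4% to 100% of the peaks of a list, q equalled p times a constant over the rank of p, with the constant to within 0.5, the form of a Benjamini-Hochberg adjustment, and stayed below 0.01. From that constant the number of candidate regions behind each list was recovered. In the minus-strand list of E13.5 the ranks left room for 2 better-ranked candidates, which were not used here. Whether the test was one-sided, and so whether a listed peak stands for more RNA in the RIP than in the input, is not stated in the lists. The lists give no read totals, so the depth of the libraries and the precision it sets are unknown. The authors' p-values were used only to rank peaks within a time point, over both strands together.

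Whether the pair of lists of a time point stood for genome strands was tested from the annotation before genes were assigned. Of peaks over exactly 1 annotated gene, between 94.1% and 97.4% in the lists named positive lay over a gene of the plus strand, and between 3.64% and 4.75% in those named negative, so the lists were read as plus and minus strand. Gene models were GENCODE vM21 on GRCm38, the assembly that mm10 names. A protein-coding gene had a peak when an exon of it on the same strand shared at least 1 bp with the peak. A peak's class was read at its midpoint on the same strand as 3' UTR, CDS, 5' UTR, noncoding exon, intron or intergenic, over all isoforms. Of 29007 peaks, 20292 touched an exon on their strand and 18912 touched an exon of a protein-coding gene. Among the 20292, 432 touched exons of 2 or more genes, and 930 were assigned first to a processed pseudogene, where reads can be shared with the parent gene.

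Genes at 2 time points were compared by two-sided Fisher's exact tests over the 6609 protein-coding genes with a peak at any time point, beside the overlap that independent lists would give. A gene was called gained when it had a peak at the later time point only and lost when it had a peak at the earlier one only. There were 26 gene lists; the 21 with at least 5 protein-coding members carrying a peak were tested by two-sided Fisher's exact tests among gained against lost genes, at each time point, and among genes with a peak at all 4 time points. Each family of tests was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A random-list comparison, with 10000 lists matched on exonic length in 10 bins, was made over all protein-coding genes and, as an added alternative, over genes with a peak.

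Positions were compared with a one-sided permutation test that placed each peak 1000 times at random in the exons of its own gene. The 3' UTR share of exonic peaks was compared with 10000 such placements, two-sided. Change of location was tested on the strongest peak of each gene with two-sided Fisher's exact tests. A test of intronic against exonic peaks between time points was added after the class shares had been seen. For sequence, each peak that lay within 1 spliced protein-coding transcript was set beside a random window of the same length on that transcript, with a two-sided sign-flip permutation test of 100000 flips. Up to 1000 pairs of at most 300 nt per time point were folded with RNAfold, and each sequence was also folded after 5 shuffles that kept its dinucleotides. Spliced transcript sequences took the place of the genome sequence, and the share of repeats was not analysed here.

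Named genes were chosen by a rule. It took Stau2 and each member of the list of reported STAU2 cargo with a peak; the 10 genes with the strongest peaks at each time point; and the 10 genes with the best mean rank among those with peaks at all 4. It also took the 5 strongest gained and the 5 strongest lost genes of each pair, and up to 4 members of each gene list with the strongest peaks. Predicted gene models were counted but not named. Further members of lists that passed a test, the genes with the most intronic peaks and the widest peaks are named too, and those were chosen after their values were seen. The groups, the comparisons, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Some genes that this rule selects are not reported here.

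Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and ViennaRNA 2.7.2. The list tests, the peak overlap, the 3' UTR share, the folding comparison and the length-matched lists were also run on simulated data; the other tests were not. In simulated gained against lost genes of E11.5 and E17.5, 21.2% of planted lists of 40 genes with an odds ratio of 4 were called. For the test at E17.5 the share was 87.2%. Many tested lists were smaller, such as reported STAU2 cargo with 10 members with a peak. Smaller lists were not simulated, so these shares do not hold for them. Unplanted lists were called in 0.344% and 0.125% of tests. Random placements passed an unadjusted p of 0.05 in 10% of simulations of peak overlap and in 8% of those of the 3' UTR share, and planted effects passed in 100% of both. These shares rest on few simulated runs, with fewer placements or draws than in the main tests. They do not show whether the tests pass too often. Alternatives covered the authors' threshold, the assignment of peaks to genes, list lengths, the background, the class rule, the isoforms, the overlap rule and the comparison window; leaving out peaks over 5000 bp and the settings of the intronic test were added after the data were seen.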

Results

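The series asked which RNAs STAU2 binds in the developing mouse cortex and how that set differs between 4 embryonic days. STAU2 is a double-stranded RNA-binding protein that takes part in the transport, localisation and stability of messenger RNAs in neurons and neural progenitors. RNA from STAU2 RIP and from input lysate was compared by the authors at E11.5, E13.5, E15.5 and E17.5, with 3 libraries of each kind per time point. The deposited lists hold peaks per time point and strand, with no values per replicate, so the spread between replicates and the read depth are unknown. Peaks and genes are not replicates: the tests below describe these lists, and a difference between time points includes any difference in depth or preparation of their libraries.

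At E11.5 the strongest peaks by the authors' p lay in Zfand3 (chr17:30135346-30135503, CDS, rank 2), in Upf2, a factor of nonsense-mediated decay (chr2:6052119-6052270, midpoint in an intron, rank 4), and in the 3' UTR of Ccdc50 (chr16:27450400-27450466, rank 5). They were followed by Atf4, the transcription factor of the integrated stress response (chr15:80256730-80257151, CDS, rank 11), by Rfng, a glycosyltransferase that modifies Notch (rank 13), and by Ttc32, Satb1, the microRNA host transcript Mir17hg, Gng3 and Arl8a. At E13.5 Sfr1 led with a 3' UTR peak (chr19:47735344-47735476, rank 2), ahead of Kansl2-ps, the histone acetyltransferase gene Kat6b (rank 6), Taok3, Supt5, Zfp395, Sik3, Ube2m, Cyb5r3 and Vps37b. At E15.5 the leading genes were Cisd1 (rank 3), Rcn2, Mycn (chr12:12936834-12936919, 3' UTR, rank 5), Xiap, Hnrnpll, Mrpl28, Actb (chr5:142903661-142903722, 3' UTR, rank 23), Mapre1, Cbfa2t3 and Ube2q1. At E17.5 the strongest peak of the time point lay in the 3' UTR of Plagl1, an imprinted zinc finger gene (chr10:13131362-13131486, p = 1.04e-08 in the authors' deposited list). Rraga, a GTPase of amino acid sensing (rank 3), Fam124a, Nfxl1, Gsk3a, Leprot, Trp53bp1, Xrcc6, the mRNA export factor Nxf1 and the calcineurin subunit gene Ppp3ca came next. Ranks hold within a time point only. Where genes are named over several days below, ranks within lists of unlike length were set side by side.

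In number, 6530 peaks were listed at E11.5, 5871 at E13.5, 10265 at E15.5 and 6341 at E17.5. They came from 29797, 30493, 27544 and 17441 candidate regions by the q-values, of which 21.9%, 19.3%, 37.3% and 36.4% were listed. The median width lay between 81 and 83 bp. Between 57 and 111 peaks per time point were over 5000 bp wide, and these held 45.2%, 51.4%, 48.3% and 31.3% of the covered bases. The widest ran over a cluster of predicted genes (chr4:41809531-42055053, minus strand, 245523 bp, E15.5), and a peak of 150782 bp covered Srp54b (chr12:55099266-55250047, E11.5). With no replicate values, no test between these counts was possible.

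**Figure D1:**
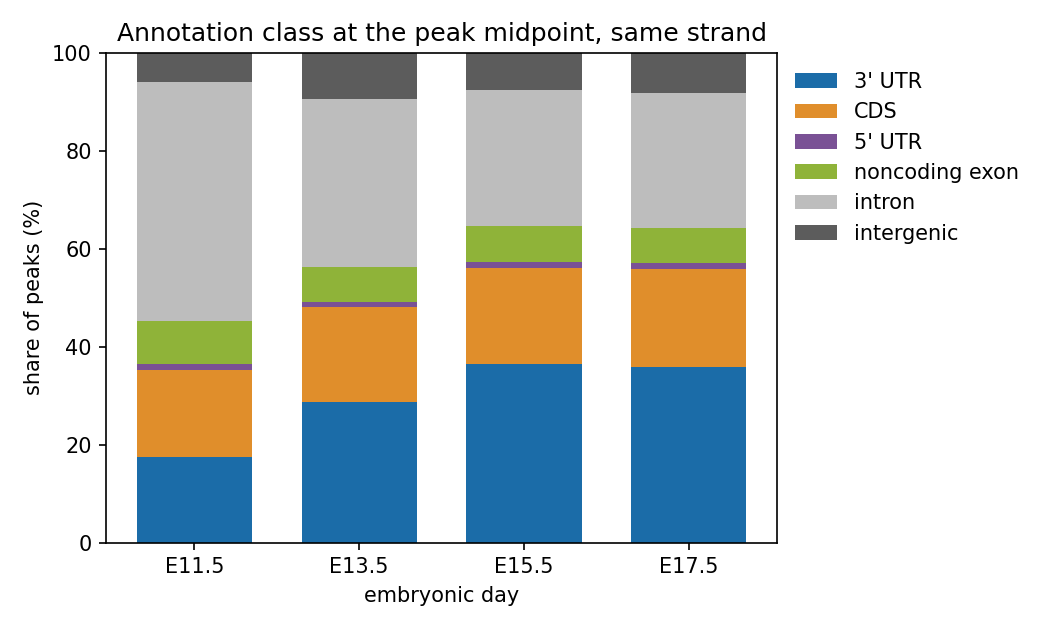
Share of peaks (percent of the peaks of a time point) by transcript class at the peak midpoint, for the 4 embryonic days. The intronic share is 48.8% at E11.5 and 27.6% at E17.5, and the 3' UTR share is 17.4% and 35.8%.

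A peak was found in an exon of 1992 protein-coding genes at E11.5, 2578 at E13.5, 4358 at E15.5 and 2972 at E17.5, which came to 6609 genes. Only 389 of them (5.89%) had a peak at all 4 time points, while 3156 (47.8%) had one at a single time point. Those with the best mean rank over the 4 time points were Celf3, an RNA-binding splicing regulator with a mean rank of 137.75, then Dgcr8, the partner of Drosha in microRNA processing, the splicing-related gene Srrm2, Atn1, the glycogen synthase kinase gene Gsk3a, the actin capping gene Capzb, Nova2, Sept3, the chromatin gene Setd5 and the actin nucleator gene Spire1. The genes listed at a single time point numbered 522 at E11.5, 501 at E13.5, 1356 at E15.5 and 777 at E17.5.

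From E11.5 to E13.5, 1726 genes were gained and 1140 lost. Taok3, Sik3, Vps37b and St3gal1 were among the genes with the strongest gained peaks, and Upf2, Ccdc50, Atf4, Rfng and Ttc32 had the strongest lost ones. From E13.5 to E15.5, 2654 genes were gained, led by Rcn2, Xiap, Mrpl28, Actb and Mapre1, and 874 were lost, led by Zfp395, Rgl2, Rnf130, Sema3a and Paqr3. From E15.5 to E17.5, 1107 were gained, led by Fam124a, Ppp3ca, Fahd2a, Sh3glb2 and Rbm17, and 2493 were lost, led by Rcn2, Mycn, Xiap, Hnrnpll and Mrpl28. Between E11.5 and E17.5, 2259 were gained and 1279 lost. Plagl1, Rraga, Fam124a, Nfxl1 and Leprot led the gains, and Zfand3, Upf2, Ccdc50, Ttc32 and Satb1 the losses. A gain or loss here is a peak that touches an exon in one list and none in the other, with no test of the gene itself. A lost gene can still hold intronic peaks: Hnrnpll, lost from E15.5 to E17.5, had 15 of them at E17.5.

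Among the 6609 genes, E11.5 and E13.5 shared 852, where independent lists would share 777 (odds ratio 1.25, adjusted exact p = 6.31e-05, Fisher's test). E11.5 shared fewer genes than independent lists would with E15.5 (1223 against 1314, odds ratio 0.752, adjusted exact p = 1.06e-06) and with E17.5 (713 against 896, odds ratio 0.582, adjusted exact p = 2.96e-22). The same held for E15.5 and E17.5 (1865 against 1960, odds ratio 0.773, adjusted exact p = 1.63e-06). E13.5 shared 1704 genes with E15.5 and 1161 with E17.5, close to the 1700 and 1159 of independent lists, with odds ratios of 1.01 and 1.00 (adjusted exact p = 0.939 for both). Leaving out genes without any peak lowers such odds ratios by construction, so values below 1 are not evidence that 2 lists avoid each other. Taking the background as all 21992 protein-coding genes turned these values, since genes without any peak then count as shared absences: every pair lay above independence, from an odds ratio of 4.38 for E11.5 and E17.5 to 12.3 for E13.5 and E15.5. With list lengths made equal the odds ratio of E11.5 and E13.5 came to 1.00 and 0.994, and that of E13.5 and E17.5 to 0.750 and 0.760. That step mainly shortened the list of E15.5 and with it the background, so these values do not show whether the excess of E11.5 and E13.5 was lost.

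Stau2 had a peak at all 4 time points. At E11.5 it lay in the CDS (chr1:16374734-16374808, rank 631), with the sequence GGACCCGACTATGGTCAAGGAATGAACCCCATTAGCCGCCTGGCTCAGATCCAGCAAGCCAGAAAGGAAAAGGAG, a GC content of 54.7% and a minimum free energy of -15.8 kcal/mol. At the later time points the strongest Stau2 peak lay in the 3' UTR, at chr1:16344817-16344950 (E13.5), chr1:16345323-16345517 (E15.5) and chr1:16344694-16344791 (E17.5). Of 17 transcripts fixed as reported STAU2 cargo, 10 had a peak at any time point: 2 at E11.5, 3 at E13.5, 8 at E15.5 and 4 at E17.5, and none at all 4. Calm3, which encodes calmodulin, had a 3' UTR peak at E11.5 (chr7:16916816-16916964, rank 180). Map1b, a microtubule-associated protein gene, had 7 peaks at E11.5, the strongest in the CDS (chr13:99434419-99434577, rank 541), and 3' UTR peaks at E15.5 and E17.5. Cplx1, which encodes the synaptic protein complexin, had 3' UTR peaks at E13.5 (chr5:108518898-108518983), E15.5 and E17.5. Ddx1 was listed at E13.5 and E17.5, Bbs2 at E15.5 and E17.5, and Actb, Bcl2l1, Limk1 and Trim32 at E15.5. The Actb peak at E15.5 read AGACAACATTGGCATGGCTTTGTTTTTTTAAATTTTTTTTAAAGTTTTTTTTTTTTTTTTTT in the transcript, 17.7% GC with a minimum free energy of -3.5 kcal/mol. The list did not pass at any time point or among gained and lost genes.

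Some genes carried peaks at the same position on several days. The 3' UTR of Capzb was covered at chr4:139291058-139291414 at E11.5, chr4:139291056-139291378 at E13.5 and chr4:139291054-139291375 at E17.5. In Gsk3a the 3' UTR peaks of E11.5 (chr7:25228418-25228573), E13.5 (chr7:25228341-25228571) and E17.5 (chr7:25228335-25228583) overlapped, and in Zfand3 the CDS peak of E11.5 overlapped that of E13.5 (chr17:30135357-30135451). Uqcrq, a subunit gene of respiratory complex III, had a CDS peak within chr11:53430561-53430643 at E11.5, E15.5 and E17.5. Overlap was counted over peaks that touched an exon of any gene on their strand, coding or not. Among them, 22.9% of those at E13.5 and 22.9% of those at E17.5 were overlapped by a peak of E15.5. Random placement in the exons of the same genes gave 10.1% ± 0.406 and 9.31% ± 0.360 (SD over placements). The lowest overlap was that of E17.5 peaks with E11.5 peaks, 6.83% against 3.20% ± 0.204. All 12 directed pairs lay 2.04 to 2.47 times above placement, each with p = 0.001, the smallest that 1000 placements can give (one-sided permutation test). Placement was uniform over the exons of all isoforms, and peaks favoured 3' UTRs. A shared preference for a part of the transcript would raise these ratios too. Placement within the same part was not run, so recurrence of single positions cannot be told apart from it.

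**Figure D2:**
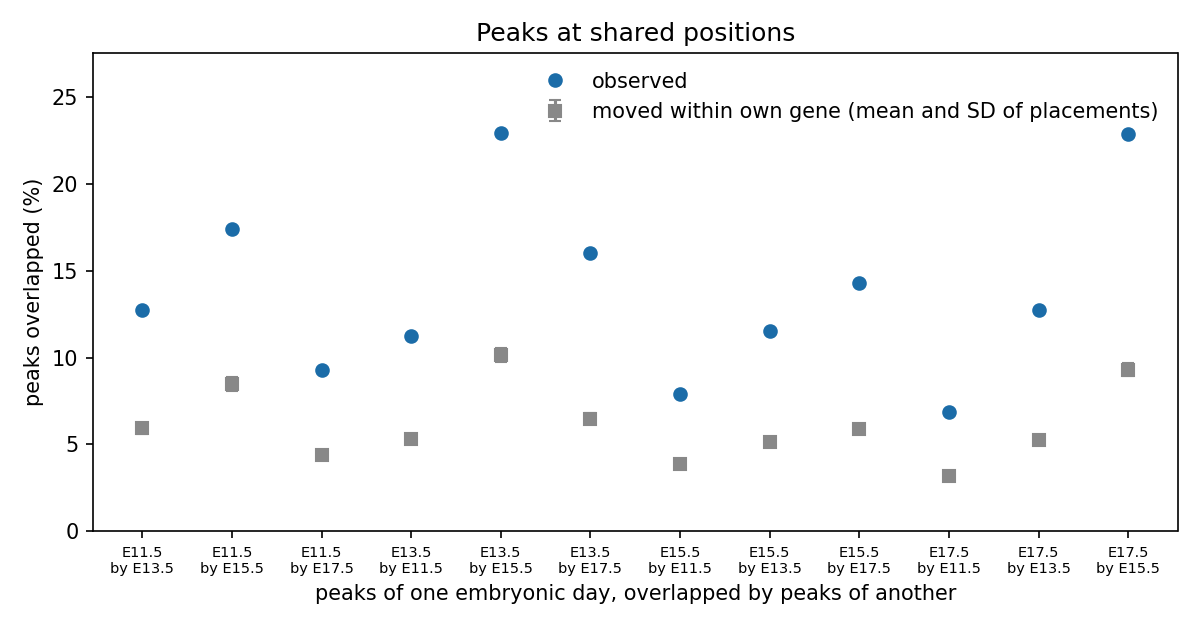
Share of exonic peaks of one embryonic day (percent) overlapped by a peak of another day, observed and after random placement in the exons of the same genes, with the SD over 1000 placements. Each observed share lies above its placements, with ratios from 2.04 to 2.47.

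Strong 3' UTR peaks were found in Ccdc50 at E11.5, Sfr1 at E13.5, Mycn and Actb at E15.5, and Plagl1 and Rraga at E17.5. The 3' UTR took 43.9% (95% interval 42.0-45.9, n = 2584 peaks) of the exonic peaks of protein-coding genes at E11.5, 55.2% (53.4-57.0, n = 3061) at E13.5, 60.0% (58.8-61.2, n = 6241) at E15.5 and 59.1% (57.5-60.6, n = 3835) at E17.5. Placement in the exons of the same genes gave 37.0% ± 0.835, 33.0% ± 0.755, 33.6% ± 0.535 and 28.0% ± 0.644, and p was 0.0002 at each time point, the smallest that 10000 draws can give (two-sided permutation test). The coding sequence held more peaks than placement at E11.5 (44.9% against 32.2%). It held fewer at E15.5 (32.1% against 35.0%) and at E17.5 (33.0% against 38.5%), and at E13.5 the difference did not pass (37.2% against 35.7%, permutation p = 0.0598). Placement also used noncoding exons of all isoforms, and the CDS comparison was not repeated on the longest isoform. There the 3' UTR share was 48.4% against 47.9% placed at E11.5, so CDS and 5' UTR together lay near placement. At E13.5 it was 58.9% against 42.2%, so CDS and 5' UTR together lay below placement. The excess in 3' UTRs at E11.5 was lost when the class was taken by any overlap (38.2%, permutation p = 0.769) or from the longest isoform only (48.4%, permutation p = 0.558); both changes left it at the later time points. The intervals are exact Clopper-Pearson intervals and cover counting error of peaks only.

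**Figure D3:**
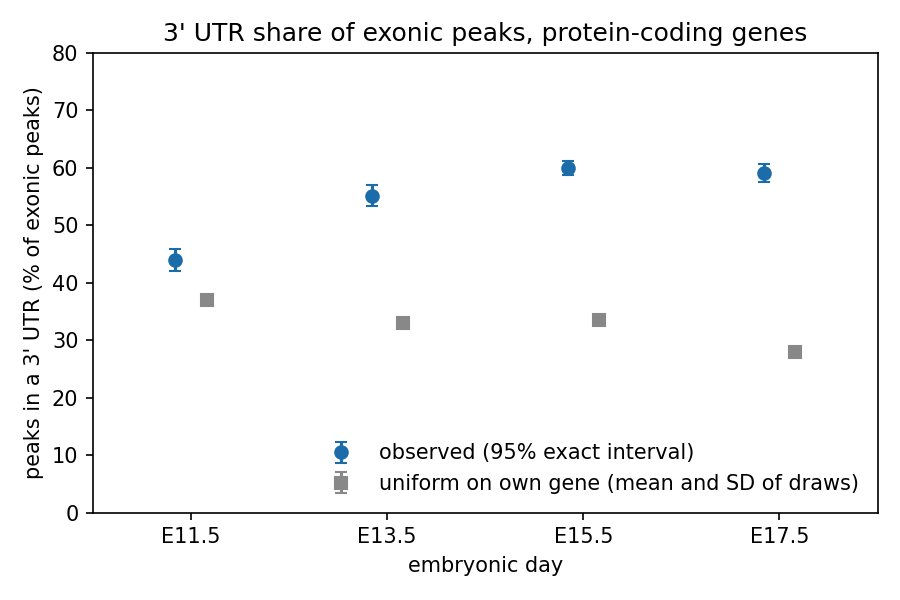
Share of exonic peaks of protein-coding genes in the 3' UTR (percent) at the 4 embryonic days, with 95% intervals, beside the share after random placement in the same exons with its SD. Observed shares run from 43.9% to 60.0% and placed shares from 28.0% to 37.0%.

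With 1 peak per gene, the 3' UTR share against the CDS rose from 50.3% at E11.5 to 62.0% at E13.5 (odds ratio 1.62, 95% interval 1.41-1.86, adjusted p = 1.04e-11, Fisher's exact test). It rose again to 66.9% at E15.5 (odds ratio 1.23, 1.10-1.39, adjusted exact p = 0.000479). It stood at 67.3% at E17.5 (odds ratio 1.02, 0.910-1.14, adjusted exact p = 0.752). Over the whole span the odds ratio was 2.03 (1.78-2.33, adjusted exact p = 9.17e-25). Stau2 went this way, from the CDS at E11.5 to the 3' UTR on later days, and so did Map1b and Spire1, while Srrm2 kept its strongest peak in the CDS throughout. Among the stronger 50% of peaks of each list the step from E13.5 to E15.5 no longer passed (odds ratio 1.07). Over all peaks, 48.8% had their midpoint in an intron at E11.5, 34.3% at E13.5, 27.7% at E15.5 and 27.6% at E17.5. Against exonic peaks the intronic ones fell from E11.5 to E13.5 (odds ratio 0.567) and from E13.5 to E15.5 (odds ratio 0.700). With 1 peak per gene the step from E13.5 to E15.5 no longer passed (odds ratio 0.884, adjusted exact p = 0.0577), and without the 20 largest hosts of each time point it was 0.869 (adjusted exact p = 0.00104). Between E15.5 and E17.5 intronic peaks did not change detectably (odds ratio 1.00, Fisher's exact test, p = 0.928), although without those hosts they were fewer at E17.5 (odds ratio 0.894, adjusted exact p = 0.00698). With 1 peak per gene the odds ratio of that step was 1.03 (adjusted exact p = 0.592).

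RNA-binding and translation control genes stood out at E11.5. Of 39 such genes with a peak at any time point, 28 had one at E11.5 (71.8% against 29.9% of other genes, odds ratio 5.97, 95% interval 2.87-13.3, adjusted p = 7.71e-06, Fisher's exact test), and 19, 28 and 18 at the later time points, where the list did not pass. The strongest at E11.5 were Celf2 (3' UTR, rank 36), Hnrnpa2b1 (CDS, rank 47), the argonaute gene Ago2 (3' UTR, rank 78) and Nova1 (rank 170). Cpeb4, Elavl4, Lin28b, Msi2, Qk and Syncrip were listed at E11.5 alone. Between E11.5 and E17.5 the list was lost more than gained: 17 members were lost, among them Ago2, Celf1, Ddx6, Elavl1, Igf2bp3 and Ptbp2, and 7 were gained, Eif4g1, Fxr2, Larp1, Rbfox1, Rbfox2, Stau1 and Tnrc6c (odds ratio 0.231, 0.0807-0.588, adjusted exact p = 0.0240). That change did not pass among the stronger 50% of peaks (odds ratio 0.343, adjusted exact p = 0.638) or with at least 50% of the peak in exons (odds ratio 0.289, adjusted exact p = 0.0749), whereas the call at E11.5 held under every alternative tried.

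Chromatin regulators were the list most often present throughout. Of 41 with a peak, 10 had peaks at all 4 time points (24.4% against 5.77% of other genes, odds ratio 5.27, 2.28-11.1, adjusted p = 0.00202, Fisher's exact test), among them Atrx, Chd2, Kdm6b, Kmt2a, Kmt2d, Kmt2e, Setd5, Smarca4 and Srcap, which encode histone methyltransferases, a demethylase and nucleosome remodellers. At E13.5 29 of the 41 had a peak (odds ratio 3.81, adjusted exact p = 0.00281), with Smarca4 (3' UTR, rank 130) and Srcap (CDS, rank 204) among the strongest, against 19, 35 and 23 at E11.5, E15.5 and E17.5. The call at E13.5 did not pass among the stronger 50% of peaks (odds ratio 1.23, adjusted exact p = 0.858) or with at least 50% of the peak in exons (odds ratio 2.36, adjusted exact p = 0.124). Of 26 pan-neuronal genes, 21 had a peak at any time point. At E13.5, 15 of these 21 had one (odds ratio 3.93, adjusted exact p = 0.0439), against 4 at E11.5 and 15 and 14 at E15.5 and E17.5. Those at E13.5 included Stmn1 (rank 314), Ank2 (rank 391), Basp1 (rank 435) and Snap25 (rank 825). Of 20 markers of vessels and meninges, 9 had a peak at any time point. Of these 9, 8 were listed at E13.5 (odds ratio 12.5, adjusted exact p = 0.0439), against 2, 3 and 0 on the other days. The 8 were Col4a1 (3' UTR, rank 183), Col1a2 (rank 364), Igf2, Col3a1, Col1a1, Col4a2, Dcn and Vtn. From E13.5 to E15.5, 6 of them were lost and 1, Cldn5, was gained (odds ratio 0.0545, adjusted exact p = 0.0265). That change did not pass among the stronger 50% of peaks (odds ratio 0, adjusted exact p = 0.638). Nor did it pass with list lengths made equal, by the strongest peaks (odds ratio 0, adjusted exact p = 0.0927) or random ones (0.103 and 0.120). The pan-neuronal and vascular calls at E13.5 rested on few genes and did not pass against lists matched on exonic length (adjusted permutation p = 0.0761 for each) or with random peaks of equal list lengths (odds ratios 4.03 and 10.7, adjusted exact p = 0.0624 for each). With the strongest peaks of equal list lengths the vascular call passed (adjusted exact p = 0.0252) and the pan-neuronal one did not (odds ratio 3.30, adjusted exact p = 0.134). The pan-neuronal odds ratio fell to 1.62 among the stronger 50% of peaks (adjusted exact p = 0.789) and to 2.22 with at least 50% of the peak in exons (0.277), where the vascular one was 13.3 and did not pass (0.0662).

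Of 83 protein-coding members of the ribosomal protein list, 17 had a peak at any time point and were tested. Of these 17, 10 had a peak at E11.5, an excess that did not pass (adjusted exact p = 0.117), 2 at E13.5, 8 at E15.5 and 1 at E17.5. At E17.5 they had a peak less often than other genes with a peak at any time point (5.88% against 45.1%, odds ratio 0.0762, adjusted p = 0.0238, Fisher's exact test). Rpl12, Rpl13, Rpl27, Rpl30, Rpl41 (3' UTR, rank 997), Rps26, Rps27l, Rps28, Rps3 and Rps6 made up the 10 at E11.5, Rps26 and Rps3 remained at E13.5, and Rpl37 was the 1 at E17.5. From E11.5 to E13.5, 8 were lost and 0 gained (odds ratio 0, adjusted exact p = 0.0240), and from E11.5 to E17.5 10 were lost and 1 gained (odds ratio 0.0562, adjusted p = 0.0232). These genes have many near-identical processed pseudogenes, so single members are uncertain. The changes did not pass among the stronger 50% of peaks (odds ratios 0.339 and 0, adjusted exact p = 0.957 and 0.638) or with the strongest peaks of equal list lengths (odds ratios 0 and 0.0675, adjusted exact p = 0.0692 and 0.0603), and that to E13.5 did not pass with gene bodies in place of exons either (odds ratio 0.0920, adjusted exact p = 0.0711). The call at E17.5 was lost among the stronger 50% (odds ratio 0, adjusted exact p = 0.357) and with random peaks of equal list lengths (odds ratio 0.0937, adjusted exact p = 0.0615). Of 80 nuclear genes of oxidative phosphorylation, 53 had a peak at any time point. Among genes with a peak they were under-represented at E15.5, with 24 of the 53 (45.3% against 66.1%, odds ratio 0.424, adjusted exact p = 0.0432), against 14, 14 and 26 on the other days. Among the peaks of the list that ranked best within their day were those of Atp5f1 (E11.5, rank 31), Ndufs3 (E17.5, rank 182) and Uqcrq (E11.5, rank 202). The direction at E15.5 turned against all protein-coding genes (odds ratio 1.74, adjusted exact p = 0.0657), and of the alternatives tried the call held only with gene bodies in place of exons. Against length-matched lists of all protein-coding genes the 24 at E15.5 were an excess (9.64 in matched lists, adjusted permutation p = 0.00131). The other days also lay above such lists (4.19, 5.88 and 6.97). That background includes silent genes, so the fewer genes at E15.5 hold only among genes with a peak.

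**Figure D4:**
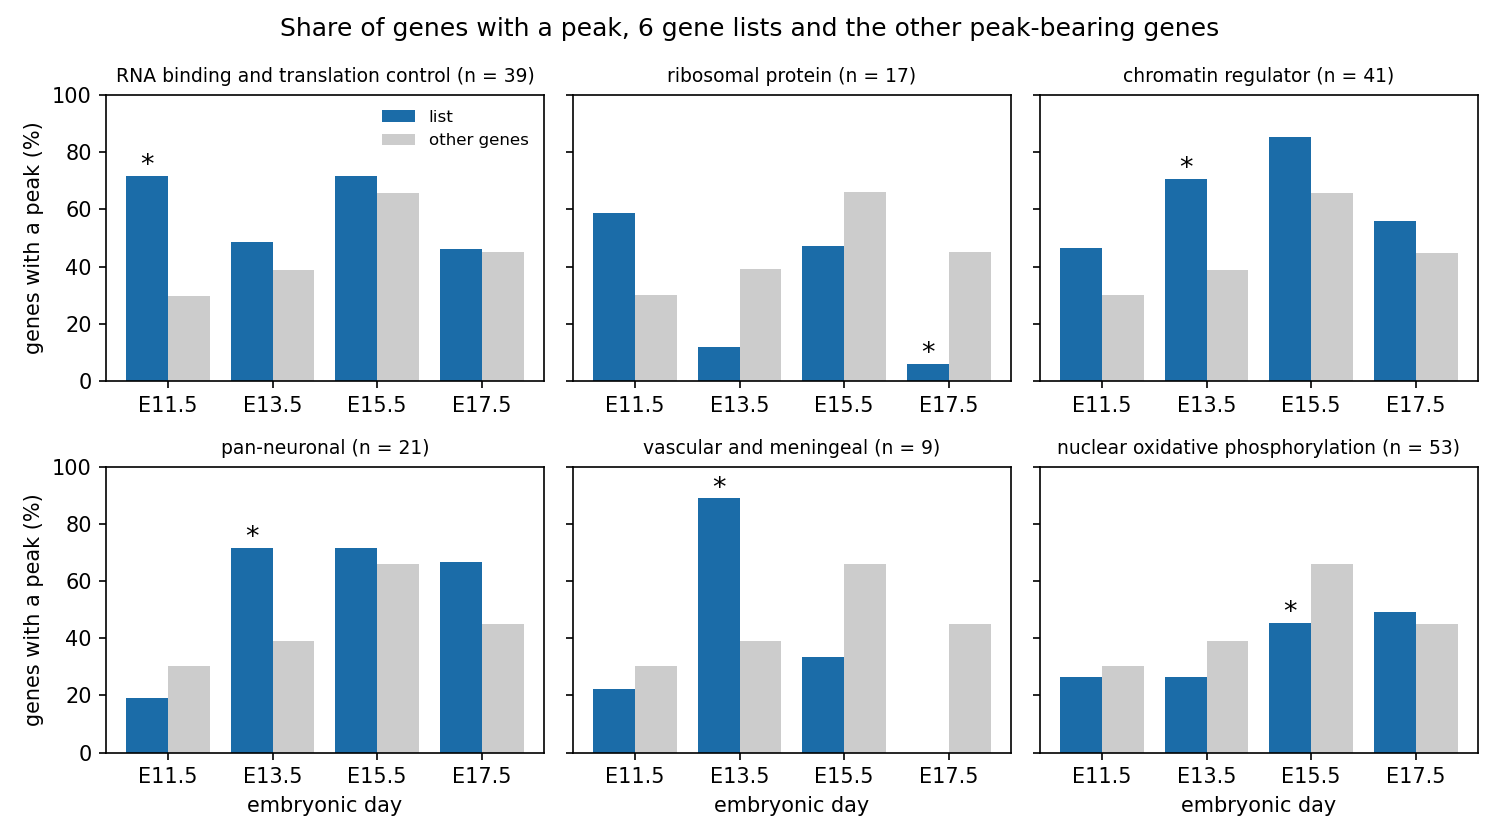
Share of list members with a peak (percent of members with a peak at any day) at the 4 embryonic days, beside the share among all other genes with a peak. Only the 6 gene lists that passed at a single time point are shown. RNA binding and translation control stands at 71.8% at E11.5 and chromatin regulators at 70.7% at E13.5.

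No other list passed with all peaks over exons. Under single alternatives calls also came up for synapse and ion channel genes at E11.5 (gene bodies, and random peaks of equal list lengths), and with such random peaks for ribosomal protein genes at E11.5 and for primary cilium genes between E15.5 and E17.5. RNA-binding genes passed for all 4 time points among the stronger 50% of peaks and against all protein-coding genes, a background that gave 41 calls at single time points. Of 84 tests among gained and lost genes 4 passed and 14 had an unadjusted p under 0.05; of 84 tests at single time points 6 passed and 20 did so unadjusted; and of 21 tests for all 4 time points 1 passed and 1 did so unadjusted. Each count that follows is out of the list members with a peak at any time point. Radial glia genes had a peak in 7, 11, 17 and 7 cases of 19 over the 4 days, with Nr2e1, Emx1, Fabp7 and Notch3 the strongest. Intermediate progenitor genes had 7, 12, 15 and 3 of 17 (Rprm, Eomes, Gadd45g and Nhlh1; Eomes encodes TBR2, their defining transcription factor). Deep-layer neuron genes had 6, 4, 7 and 4 of 11 (Nfia, Fezf2, Foxp1 and Nfib), upper-layer genes 3, 2, 4 and 5 of 7 (Cux1, Lmo4, Pou3f3 and Dok5) and interneuron genes 3, 2, 6 and 5 of 12 (Sst, Lhx6 and Calb2). Cell cycle genes had 10, 9, 19 and 5 of 24 (Mki67, Cdc25b, Cdk4 and Ccnd2), and centrosome and spindle genes 11, 15, 21 and 12 of 32 (Wdr62, Incenp, Cenpe and Tpx2). Primary cilium genes had 4, 4, 8 and 12 of 19 (Ift88, Ift57, Bbs7 and Kif3b), and Wnt, Notch and Shh signalling genes 13, 12, 15 and 7 of 26 (Tcf7l2, Gsk3b, Notch3 and Lrp6). Axon guidance genes had 2, 8, 14 and 8 of 21 (Sema3a, Sema5a, Efna2 and Plxna2), atypical cadherin and adhesion genes 2, 9, 10 and 12 of 17 (Afdn, Cdh2, Cntn2 and Ctnnd2) and synapse and ion channel genes 2, 12, 20 and 16 of 27 (Gria2, Shank1 and Gabbr1). Zinc finger genes had 40, 46, 72 and 51 of 120 (Zfp395, Zfp747, Zfp414 and Zfp598), and genes of the astrocyte and oligodendrocyte lineage 0, 4, 3 and 1 of 5 (Mt3, Ncan, Sparcl1 and Bcan). The remaining lists had fewer than 5 such members and were not tested: microglia genes had Csf1r only (E13.5 and E15.5), erythroid genes Hba-x only (E11.5), replication-dependent histones Hist3h2a and Hist3h2ba (E15.5 and E17.5), and mitochondrially encoded genes none. Long noncoding RNAs, outside the protein-coding background, had a peak in 6, 4, 5 and 4 cases of 9, with Rian, Snhg1, H19 and Pantr1 the strongest.

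Peaks were compared in sequence with random windows of the same transcripts. GC content did not differ detectably at E11.5 (49.6% ± 10.0 against 49.2% ± 11.9, SD, n = 2253 pairs, permutation p = 0.136). Peaks were lower in GC by 2.02 points at E13.5 (SE 0.257, n = 2729), by 2.60 points at E15.5 (SE 0.174, n = 5630) and by 2.27 points at E17.5 (SE 0.218, n = 3439), each with a permutation p of 1e-05, the smallest that 100000 flips can give. Minimum free energy per base was higher in peaks, so that they folded less stably, by 0.0254, 0.0302, 0.0208 and 0.0287 kcal/mol at the 4 time points (n = 1000 pairs each, permutation p = 1e-05). After subtraction of shuffled copies of the same sequences the difference was not detectable, with values from 0.000531 to 0.00112 and permutation p from 0.518 to 0.776. With windows drawn from the same part of the transcript the lower GC at E13.5, E15.5 and E17.5 was reversed, to 0.388, 0.230 and 0.898 points higher in peaks, of which only the last passed (adjusted permutation p = 4e-05). At E11.5 GC was then 1.73 points higher in peaks and passed (adjusted permutation p = 4e-05). The folding differences fell to 0.0151, 0.00835, 0.00284 and 0.0132 kcal/mol per base, and the one at E15.5 no longer passed (adjusted permutation p = 0.397).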

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

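The test of intronic against exonic peaks, its repeat with 1 peak per gene, the list comparison matched on exonic length among genes with a peak and the recount of the largest host genes were chosen only after the results they bear on had been seen.

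Intronic peaks differed between the time points. Against exonic peaks they fell from E11.5 to E13.5 with an odds ratio of 0.567, from E13.5 to E15.5 with 0.700 (0.884 with 1 peak per gene, which did not pass), and from E11.5 to E17.5 with 0.398 (51.9% against 30.0%). A few genes held many of them: at E11.5 Gpc4, a glypican gene, had 141 intronic peaks, Reep3 118, Plekha5 109, Rps6ka3 101 and Nfib 94, and at E13.5 Xpo7 had 182. A few such hosts did not account for the difference, since without the 80 genes that were among the 20 largest hosts of any time point the odds ratio was 0.425, and weak peaks did not either, since among the stronger 50% it was 0.340. If 1 signal over a host was listed as many peaks, the spread of p within hosts should be low. Within hosts of at least 10 intronic peaks the SD of log10 p was 0.396. Shuffling p-values among these hosts gave a mean of 0.581 (permutation p = 0.001, the smallest that 1000 shuffles can give). The predicted lower SD was met, but any difference in the level of p between hosts would give it too. The test therefore cannot tell whether 1 signal was listed as many peaks. With 1 peak per gene, the best-ranked one, the odds ratio of E17.5 against E11.5 was still 0.589, so counting each gene once did not remove the difference. A host with many intronic peaks is still more likely to have an intronic one ranked first. How much of the difference such splitting covers therefore cannot be told from this value. A higher share of unspliced RNA at E11.5, either in the tissue or in what the RIP recovered, stays open and was not tested, as does any difference between the libraries of the 2 days.

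RNA-binding and translation control genes were lost more often than gained between E11.5 and E17.5, with an odds ratio of 0.231, after their excess at E11.5. The loss did not pass among the stronger 50% of peaks (odds ratio 0.343, adjusted exact p = 0.638). With at least 50% of the peak in exons it did not pass either (odds ratio 0.289, adjusted exact p = 0.0749). The checks that follow concern the excess at E11.5 only. Long exonic sequence does not explain the excess, since random lists of genes with a peak and of like exonic length had 12.8 members with a peak at E11.5, against 28. Peaks that merely touch an exon do not explain it either, since with at least 50% of the peak in exons the odds ratio was 4.75. The level of these transcripts in the cortex at E11.5 stays open, because input values per gene were not used here, and a change in what STAU2 binds was not tested apart from it.

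Other differences between time points were these. Ribosomal protein genes were gained against lost with an odds ratio of 0 from E11.5 to E13.5 and of 0.0562 from E11.5 to E17.5. Vascular and meningeal genes had 0.0545 from E13.5 to E15.5. The 3' UTR against the CDS had odds ratios of 1.62 from E11.5 to E13.5, 1.23 from E13.5 to E15.5 and 2.03 from E11.5 to E17.5.

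Peaks with their midpoint in no gene of their own strand, counted as intergenic, numbered 388 at E11.5, 556 at E13.5, 776 at E15.5 and 517 at E17.5. Of these, 193, 281, 357 and 252 lay over a gene of the opposite strand.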

How the results depend on the processing

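Peaks over 5000 bp left out, lists matched on exonic length among genes with a peak, and every setting of the intronic test were added after the data had been seen; the other alternatives given here were planned. Single gene-list calls were tallied apart. Among the other values that answer a comparison, 152 were kept. These held their direction and their side of the threshold, passed in neither setting or, for counts, stayed within 1.5-fold. Another 13 changed direction and passed in at least 1 setting, 5 no longer passed, 3 newly passed and 16 counts changed by more than 1.5-fold. All of those are given below. For single gene-list calls, 53 values were kept, 28 no longer passed and 1 changed direction. Odds ratios that were not finite are outside these counts. Peak positions overlapped above placement under every overlap rule tried. RNA-binding genes at E11.5 kept odds ratios from 4.50 to 6.17, and chromatin regulators at all 4 time points from 4.84 to 7.19, rising to 15.0 and 15.4 against all protein-coding genes.

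The stronger 50% of each list left 3264, 2935, 5132 and 3170 peaks by construction, with 1131, 1511, 2752 and 1842 genes and 93 at all 4 time points. It gave 0 list calls among gained and lost genes, 1 at single time points and 2 for all 4, and odds ratios of 0.846 for E11.5 with E13.5, 0.589 for E13.5 with E15.5 and 0.722 for E13.5 with E17.5. The 3' UTR step from E13.5 to E15.5 became 1.07. Fewer peaks enter there. With the strongest peaks of equal list lengths the odds ratios were 1.00 (E11.5 with E13.5) and 0.750 (E13.5 with E17.5), with 1 gained or lost list call; with random peaks they were 0.994 and 0.760. At least 50% of the peak in exons gave 0.884 for E13.5 with E15.5 and 2 list calls at single time points. For these the cause was not tested.

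All protein-coding genes as background gave odds ratios of 8.56 and 4.38 for E11.5 with E15.5 and E17.5, 12.3 and 7.96 for E13.5 with the same, and 11.2 for E15.5 with E17.5, since genes without peaks then count as shared absences. It gave 41 list calls at single time points and 2 for all 4, and oxidative phosphorylation at E15.5 turned to 1.74. The 3' UTR share at E11.5 was 38.2% by any overlap and 48.4% on the longest isoform. Windows from the same part of the transcript gave GC differences of 1.73, 0.388, 0.230 and 0.898 points at the 4 time points, and a folding difference of 0.00284 at E15.5. The cause was not tested. For vascular genes at E13.5 the odds ratio was not finite among the stronger 50%, where the call was lost (adjusted exact p = 0.117), and with the strongest peaks of equal list lengths, where it was kept (adjusted exact p = 0.0252).

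No paired analysis was possible because each time point has 1 list over all its libraries and no column per replicate. For the same reason leaving out 1 replicate at a time was not possible. Depth is unknown, and how far it limited each list was not tested: the q-values imply 17441 candidate regions at E17.5 and 30493 at E13.5.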

Other observations

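The comparison of base composition, the recount of intronic hosts at other time points and the folding test by time point were chosen only after the results they bear on had been seen.

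Intronic peaks of E13.5 were led by Xpo7, a nuclear transport receptor gene (182), Taf3 (58) and Chst8 (57), those of E15.5 by Gsk3b (83), a RIKEN transcript (70), Memo1 (58) and Ireb2 (57), and those of E17.5 by Gli3, a transcription factor of Shh signalling (79), Plcg1 (64) and Chd7 (38). The 20 largest hosts of a day held 35.7%, 38.0%, 22.3% and 31.0% of its intronic peaks from E11.5 to E17.5. Of these hosts, 12 of the 20 at E11.5, 13 at E13.5, 18 at E15.5 and 14 at E17.5 had no intronic peak at any other time point. The hosts were chosen by their count on that day, and the like share over all intronic hosts was not computed. Whether the largest hosts are more particular to a day than other hosts therefore cannot be judged. Among the hosts of E11.5, Sox6 and Nfib, both transcription factor genes, had 87 and 94 intronic peaks then and 0 later. No explanation for this was tested.

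Against random lists of all protein-coding genes of like exonic length, 28 of 105 list tests lay above and 1, ribosomal protein genes at E17.5, below. Intermediate progenitor genes had a peak in 12 cases at E13.5, against 2.46 in matched lists (SD 1.47, adjusted permutation p = 0.00131), and cell cycle genes in 19 at E15.5, against 7.49 (SD 2.36, adjusted permutation p = 0.00131). Expression could not be matched, and that background includes silent genes. Among genes with a peak at any time point neither passed (adjusted permutation p = 0.172 and 0.619). Among genes with a peak, 3 tests lay above matched lists and 2 below; the one not already described was that of synapse and ion channel genes at E11.5, with 2 of 27 against 9.56 (adjusted permutation p = 0.0336), where Fisher's exact test had an adjusted p of 0.0921.

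Peaks held less G than random windows of the same transcripts at every time point, by -2.93, -2.69, -1.94 and -2.52 percentage points. With windows from the same part of the transcript the differences were -1.81, -1.05, -0.455 and -0.676 points, each with an adjusted permutation p under 0.05. In the same windows C was higher in peaks, by 3.54, 1.43, 0.686 and 1.57 points. With windows from any exon the differences in C were 3.36, 0.667, -0.662 and 0.249 points, of which the last did not pass (adjusted permutation p = 0.220). The direction for C at E15.5 thus depended on the window. Base composition is a candidate explanation for the less stable folding of peaks, since after subtraction of dinucleotide shuffles the largest difference over the 4 time points was 0.647 SE. The part of the transcript, such as more 3' UTR sequence in peaks, could account for it at E15.5, where windows from the same part left 0.00284 kcal/mol per base. It could not account for the whole at E11.5, E13.5 and E17.5, where at least 0.00835 was left. Windows were matched on 5' UTR, CDS and 3' UTR alike, so 3' UTR sequence was not tested apart from the other parts. Whether the composition comes from STAU2 binding or from the library preparation was not tested, since input peaks were not analysed here.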
